A study of Mus musculus with 40 samples.

How the data were processed

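RNA was measured in colonic epithelial cells and in total colonic tissue of mice that had received 2000000 sorted Tritrichomonas musculis (T.mu), a protozoan of the mouse gut, or no inoculum. Samples were taken 3, 14 and 48 days later. The 40 libraries fall into 12 groups of tissue, day and inoculum, with 3 libraries per group at days 3 and 14 and 4 at day 48. Each library is one replicate. The series design names 3 different mice per group, which is less than the 4 libraries per group at day 48, so that these 4 are separate mice rests on their litter labels. Group, day and litter were taken from the sample labels.

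The deposited table holds whole-number counts per gene, 1 column per library, without normalization. The libraries were 3′ digital gene expression libraries, which sequence the ends of transcripts, per the labels' protocols. STAR and Subread are named per the submitters' processing notes, without a version, setting or role. The genome build, the annotation, the strand of counting and any use of molecular identifiers are not given in the labels, so counting intervals and floors cover counting error only. The table has 45792 mouse gene IDs, of which 45143 (98.6%) have a symbol in the GENCODE M21 reference (GRCm38), and these symbols are used here. A remaining entry is not a mouse gene. It holds 269150 of the 69164307 deposited counts (0.389%) and was left out of library sizes and tests, and is reported separately as non-mouse CPM, taken of all counts of a library. Between 61.2% and 87.2% of the small values above 0 are even in each library, as when both mates of a read pair are counted, so the precision of low counts is below what the numbers imply.

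Total counts ranged from 170297 to 2867502 per epithelial library (median 1166986; 3 libraries below 400000) and from 220733 to 6756802 per tissue library (median 2176603; 4 below 400000). No library was below the minimum of 100000 counts. Ribosomal RNA genes together with Lars2, a gene that overlaps ribosomal RNA sequence, took 25.6% to 46.6% of the counts in epithelium and 8.96% to 29.5% in total tissue. Replicates of a group differed by more than counting error, with chi-square values per degree of freedom from 2.75 to 61.3.

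Counts were tested with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3), with genes kept by filterByExpr (minimum count 10, minimum total 15), TMM scaling and robust dispersion estimates. One fit per tissue covered its 20 libraries and 6 groups, and one fit over all 40 libraries served the comparisons between tissues. T.mu was compared with control on each day, as the mean over days, and for a difference between days (a test with 2 degrees of freedom). Differences between tissues were tested as interaction contrasts, and control epithelium was compared with control tissue. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05. Log2 fold changes are given with their standard errors, and levels as TMM-scaled CPM of the mouse counts with the SD over replicates. Non-mouse CPM were compared by exact two-sided permutation tests.

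Gene lists were tested with camera (limma 3.58.1, correlation preset at 0.01) where at least 5 members were kept, with Benjamini-Hochberg adjustment over the lists of a comparison. Before the data were examined, 34 lists of cell types, pathways and quality markers were fixed, along with the designs, the alternatives and the rule for named genes. Pathway lists were inflammasome and IL-1 family, antigen presentation by MHC class II, interferon-gamma response, type I interferon response, epithelial antimicrobial and IL-17/IL-22 response, type 2 immune response, T and innate lymphoid effector genes, fatty acid oxidation and ketogenesis, cholesterol and lipid synthesis, xenobiotic metabolism, nuclear-encoded mitochondrial respiration and ER stress. Cell type lists were tuft, goblet, T, B and plasma, germinal centre, macrophage and dendritic, neutrophil and inflammatory myeloid, eosinophil and mast, absorptive colonocyte, stem and proliferating, enteroendocrine, smooth muscle, fibroblast and matrix, endothelium and lymphatics, enteric neuron and glia, adipocyte, red blood, and Paneth and small intestine. The remaining lists were mitochondrially encoded genes, cytoplasmic ribosomal proteins, immediate early and heat shock genes and circadian clock. Neutrophil and eosinophil lists had too few expressed members to be tested in either tissue. Red blood cell genes could be tested in epithelium alone, and the type 2, T and innate lymphoid effector, T cell, macrophage and endothelium lists in total tissue alone.

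Named genes were, per comparison, up to 10 higher and up to 10 lower genes with the smallest adjusted p among those that moved the same way in every litter pair. Up to 4 members per list past the threshold were added, or the 2 members with the smallest p where a list was called with none past it. A short list of genes was named always, whatever its result (Casp1, Cd74, Cxcl9, Dclk1, Ifng, Igha, Il17a, Il18, Il1b, Il22, Il25, Muc2, Nlrp1b, Pycard, Reg3g and Retnlb). A fold against a group without counts was computed against a floor of 3 counts over the group and is given as a lower bound. With 1 to 3 counts in a group, the ratio is given with its 95% counting interval. Genes with close copies, such as Ifi27l2a and Ifi27l2b, the Oas, Oasl, Ifit, Irgm, Igtp, Trim30, Apol9, Gsdmc, Sprr, Hbb, Rpl and H2 families, may share reads, and their single values are uncertain.

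The labels give a litter to every library, so libraries with the same number on a day were taken as litter pairs. In the data, 3 of the 20 litter pairs deviated together with a correlation above 0.1, 7 correlated best with their own litter, and correlations ran from -0.103 to 0.186. Same-numbered libraries of the 2 tissues gave no correlation above 0.1 among 20 pairs (median 0.00489). They share day, inoculum and litter; the labels do not state that they come from 1 animal, and the block called the animal here rests on the number.

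Alternatives were a fit with the litter (or, between tissues, the animal) as a replicate block, DESeq2 1.42.0, DESeq2 size factors in edgeR (RLE), limma voom with sample weights, no filter beyond 1 read, only the libraries of a comparison, each library left out in turn, and for lists an estimated correlation and fry. Chosen after seeing the data were counts halved (and rounded up), a fit without ribosomal RNA genes and Lars2, a fit without libraries under 400000 counts, and a correction for GC content and transcript length in the fit with the litter block. The procedure was tested on simulated data with 200 changed genes per comparison. It called 104, 135 and 133 genes for epithelium at days 3, 14 and 48 and 154, 140 and 141 for tissue, of which 1.43% to 5.26% were false. It recovered 64% to 90.6% of genes changed 4-fold and 14.3% to 37.3% of those changed 2-fold. These rates need not hold for the real libraries. In a check of X- and Y-linked genes against the labels, 1 library did not match the others of its tissue; it was kept.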

Results

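Gene expression was measured by 3′ counting in colonic epithelial cells and in total colonic tissue of mice given the protozoan T.mu and of uninoculated controls, at days 3, 14 and 48. Each tissue had 20 libraries, with 3 per group at days 3 and 14 and 4 per group at day 48. Median depth was 1166986 counts per library in epithelium and 2176603 in total tissue, and 10119 and 11696 genes were tested. Depth was uneven between arms. Control and T.mu group medians were 327141 and 844256 counts in epithelium at day 3, 1067462 and 1152580 at day 14, and 1442802 and 1611678.5 at day 48. In total tissue they were 3980605 and 2504610 at day 3, 351625 and 2129747 at day 14, and 3325423.5 and 506144 at day 48.

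Which libraries carried counts on the single non-mouse entry of the table? In total tissue its level was 26160 ± 18300 CPM (mean ± SD) with T.mu and 23.3 ± 5.42 in controls at day 3, 13794 ± 8573 and 198 ± 274 at day 14, and 6889.2 ± 4809 and 252 ± 478 at day 48. In epithelium the levels were 1033.1 ± 905 and 51.9 ± 18.3 at day 3, 747 ± 668 and 46.9 ± 9.66 at day 14, and 149 ± 179 and 32.1 ± 9.54 at day 48. In epithelium the T.mu mean was 513 without replicate 1 at day 3, 365 without replicate 2 at day 14 and 60.2 without replicate 1 at day 48. In total tissue the control mean was 40.9 without replicate 1 at day 14 and 12.7 without replicate 2 at day 48. Every T.mu library lay above every control of its comparison. In epithelium at day 48 the nearest pair, 45.2 and 43.4 CPM, was within counting error. The exact permutation p was 0.1 for comparisons of 3 with 3 and 0.0286 for those of 4 with 4. They are the lowest that 20 and 70 splits can give, and were 0.1 and 0.0858 adjusted over the 6 comparisons. The labels do not say what the entry is, so its link to the parasite rests on its distribution alone.

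**Figure D1:**
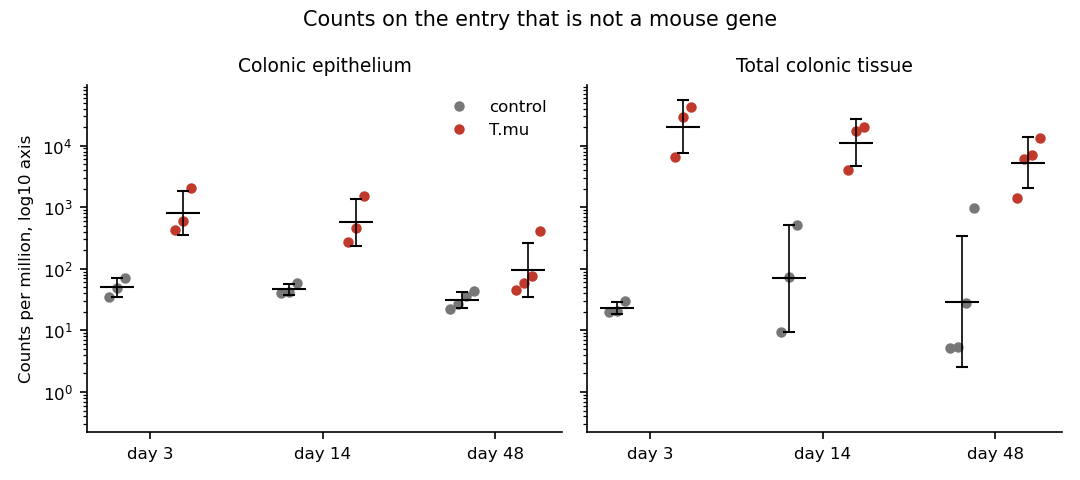
Non-mouse CPM (log scale) per library, by tissue, day and inoculum, with libraries as points and the mean and SD of the log values as bars. T.mu means ran from 149 to 1033.1 in epithelium and 6889.2 to 26160 in total tissue. Each T.mu library lay above its controls, barely so in epithelium at day 48.

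How did the 2 preparations differ without the parasite? In control mice 6249 of 11834 genes differed between epithelium and total tissue (2734 higher and 3515 lower in epithelium; 3626 and 2667 of 6293 with RLE scaling, which moved the median log2 fold change of all genes from -0.0685 to 0.184). Wfdc2, a secreted epithelial protease inhibitor, was 43.4-fold higher in epithelium (log2 5.44 ± 0.18, adjusted p = 8.91e-44). The enteroendocrine hormone gene Insl5 was 181-fold higher and Tff3, the goblet cell trefoil factor, 4.41-fold. Dcn, a matrix proteoglycan of fibroblasts, was 95.1-fold lower (adjusted p = 3.98e-41), and the smooth muscle genes Mylk and Tagln were 18.1-fold and 245-fold lower. Plasma cell genes Igkc and Jchain were 29.7-fold and 35.6-fold lower, and the myeloid genes Lyz2 and Apoe 76.9-fold and 209-fold lower. The surface colonocyte genes Krt20 and Car1 were also lower in the epithelial cells, 12.3-fold and 4.37-fold, and Irf7, the interferon-induced transcription factor, was 9.2-fold lower. Ly6g and Cd177, known best as neutrophil surface genes, were 558-fold and 14.4-fold higher in epithelium. Of the 128 named genes called, 123 kept their call whichever library was left out, and a block for the animal ended the call of Neil1 (adjusted p = 0.0525). Leaving out single libraries gave 5705 to 6327 genes.

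What changed in epithelium at day 3? With 3 libraries per arm, 36 of 10119 genes passed, 33 higher and 3 lower with T.mu. Irf7 was 6.95-fold higher (log2 2.80 ± 0.33, adjusted p = 9e-08), at 291.9 ± 83.2 CPM against 39.77 ± 14.2. Lgals3bp, a secreted galectin ligand induced by interferon, was 5.22-fold higher (log2 2.38 ± 0.29, adjusted p = 9e-08), and Oasl2, an oligoadenylate synthetase-like antiviral gene, 15-fold (log2 3.91 ± 0.50, adjusted p = 3.62e-07). Rtp4, an interferon-induced chaperone, rose 18.2-fold (adjusted p = 6.6e-05) and Ifi27l2b 4.93-fold (adjusted p = 2.26e-06). Lgals9, a galectin that signals to T cells, rose 2.97-fold (adjusted p = 0.000863) and Ifitm3, a restriction factor of viral entry, 4.06-fold (adjusted p = 0.00218). Ifi27l2a (150 counts against 0) was at least 24.4-fold higher and the ISG15-conjugating enzyme gene Ube2l6 (78 against 0) at least 12.7-fold. Oas3 was higher by a ratio of 31.2 (95% counting interval 8.46 to 260). Outside the interferon genes, the glutathione transferase gene Gstm3 was 4.05-fold higher (adjusted p = 0.00657). The lysosomal sulfatase gene Ids was 5.76-fold lower (9.727 ± 7.78 CPM against 65.55 ± 7.84, adjusted p = 0.000715) and Slit2, an axon guidance ligand, 12.1-fold lower (adjusted p = 0.0135). Cd74 (log2 -0.58, adjusted p = 0.878), the goblet cell genes Muc2 (-0.16, adjusted p = 0.863) and Retnlb (1.25, adjusted p = 0.683), Il18 (-0.90, adjusted p = 0.361), Casp1 (-0.27, adjusted p = 0.802), Pycard (0.19, adjusted p = 0.819), Reg3g (1.59, adjusted p = 0.56) and the tuft cell gene Dclk1 (0.32, adjusted p = 0.901) did not pass. Of the 16 named genes called, 12 kept their call whichever library was left out. The count was 18 without control replicate 1 and 23 without control replicate 3. The count was 6 with limma voom, 12 with only the libraries of this comparison, 20 with counts halved and 10 without libraries under 400000 counts, which leaves 1 control and 2 T.mu libraries. The litter block ended the calls of Hbb-bs (5.12-fold higher, adjusted p = 0.0129; 0.0717 with the block) and Trappc8 (4.25-fold lower, adjusted p = 0.0432; 0.108 with the block).

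By camera, 6 of 27 lists were called at day 3 in epithelium, 2 with an estimated correlation and 2 by fry. Type I interferon response genes had a median log2 fold change of 2.13, with 11 of 32 members higher (21 adjusted over the list alone, adjusted p = 1.89e-33). The 11 became 7 without control replicate 1 or 2, 1 with limma voom and 3 without libraries under 400000 counts. Interferon-gamma response genes had a median of 0.771, with 0 of 21 members past the threshold (3 adjusted over the list alone, adjusted p = 3.4e-05). These 2 lists also held with an estimated correlation (adjusted p = 5.55e-05 and 0.00232). Red blood cell genes (median 2.5, Hbb-bs of 6 members higher, 4 adjusted over the list alone, adjusted p = 0.00587) had adjusted p = 0.271 with an estimated correlation. Stem and proliferating cell genes (median 0.264, 0 of 39 members, 1 adjusted over the list alone; Mcm2 at log2 2.33 and Mcm6 at 1.21, adjusted p = 0.038) had adjusted p = 0.509 with an estimated correlation. Cholesterol and lipid synthesis genes (median 0.394, 0 of 29 members and 0 adjusted over the list alone; Fasn at 0.89, adjusted p = 0.038) had adjusted p = 0.848 with an estimated correlation. The mitochondrially encoded genes (median -0.617, 0 of 9 members and 0 adjusted over the list alone; mt-Rnr2 at -0.95 and mt-Rnr1 at -0.98, adjusted p = 3.4e-05) had adjusted p = 0.622 with an estimated correlation. The stem and cholesterol calls also ended with counts halved (adjusted p = 0.0913 and 0.0955) and without libraries under 400000 counts (adjusted p = 0.766 and 0.845), where 1 control library is left and is assumed to vary like the other groups. Counts halved brought in fatty acid oxidation genes as higher (adjusted p = 0.129; 0.0405 with counts halved). Fold changes rose with the GC content of genes (Spearman 0.35). A correction for GC content and length left 20 genes higher and 6 lower, against 29 and 4 in the same fit with the litter block and no correction. It ended the call of Gstm3 (adjusted p = 0.0621).

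What changed in epithelium at day 14? Of 10119 genes, 51 passed with 3 libraries per arm, 34 higher and 17 lower. A correction for GC content and length gave 59 higher and 71 lower, against 51 and 42 in the same fit with the litter block and no correction, so which direction holds more genes depends on it. Oasl2 was 12.6-fold higher (log2 3.65 ± 0.40, adjusted p = 1.03e-08), Oas3 15.9-fold (3.99 ± 0.58, adjusted p = 1.58e-05), Lgals3bp 3.32-fold (1.73 ± 0.26, adjusted p = 2.45e-05) and Ifi27l2a 14.1-fold (adjusted p = 5.24e-05). The ratio was 95.3 for Ifi44 (95% counting interval 16.8 to 3800) and 45.2 for the ubiquitin-like gene Isg15 (12.2 to 378). Cd74, the MHC class II invariant chain, was 15.2-fold higher (log2 3.93 ± 0.68; 81.76 ± 58.8 CPM against 5.365 ± 3, adjusted p = 0.00183), and H2-Ab1 9.73-fold (3.28 ± 0.54; 66.71 ± 44.3 CPM against 7.14 ± 5.18, adjusted p = 0.000113). The peptide transporter gene Tap1 was 6.24-fold higher (64.38 ± 20 CPM against 10.21 ± 1.04, adjusted p = 5.24e-05), and the immunoproteasome genes Psmb9 and Psmb8 5.63-fold (adjusted p = 0.00298) and 3.5-fold (adjusted p = 0.00896). Cd177 was 3.01-fold higher (log2 1.59 ± 0.29, adjusted p = 0.00101). Lower genes included Insl5, 2.46-fold lower (49.26 ± 18 CPM against 120.7 ± 20.4, adjusted p = 0.011), Tff3, 2.04-fold lower (1926 ± 398 against 3934 ± 530, adjusted p = 0.042), and the cytochrome P450 gene Cyp2c55, 1.96-fold lower (adjusted p = 0.0232). The ribosomal protein genes Rpl37a (2.3-fold lower, adjusted p = 0.00851), Rps28 (2.12-fold lower) and Rpl34 (2.04-fold lower, adjusted p = 0.017 each) were also lower. Muc2 (log2 -0.50, adjusted p = 0.463), Il18 (-0.37, adjusted p = 0.776), Retnlb (0.73, adjusted p = 0.853) and Reg3g (0.55, adjusted p = 0.876) did not pass. Of the 27 named genes called, 11 kept their call whichever library was left out. The count was 27 without T.mu replicate 1, 19 without T.mu replicate 3, 21 without control replicate 1 and 20 without control replicate 2. The count was 93 with the litter block, 95 with DESeq2, 98 with limma voom, 262 with only the libraries of this comparison, 80 with counts halved and 90 without libraries under 400000 counts. The block brought in Mvk (log2 1.92, adjusted p = 0.0644; 0.0293 with the block), mt-Rnr2 (-1.15, adjusted p = 0.156; 0.0255) and mt-Rnr1 (-1.11, adjusted p = 0.268; 0.0391).

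Of 27 lists, 11 were called at day 14 in epithelium, 4 with an estimated correlation and 6 by fry. The median of the type I interferon response genes was 1.92, with 12 of 32 members higher (23 adjusted over the list alone, adjusted p = 3.99e-40), and interferon-gamma response genes a median of 1.56, with 6 of 21 (15 adjusted over the list alone, adjusted p = 9.36e-23). The 12 became 7 without T.mu replicate 3 or control replicate 2, and the 6 became 2 without T.mu replicate 1 or 3 or control replicate 1 or 2 and 3 without control replicate 3. Genes of antigen presentation by MHC class II had a median of 2.73, with Cd74 and H2-Ab1 higher among 7 (4 adjusted over the list alone, adjusted p = 4.8e-06). Enteroendocrine genes had a median of -0.648, with Insl5 lower among 16 members (4 adjusted over the list alone, adjusted p = 1.02e-05; 0 lower without T.mu replicate 1 or 2 or control replicate 1). These 4 calls also held with an estimated correlation (adjusted p = 1.38e-05, 7.46e-07, 0.00323 and 0.0203). Ribosomal protein genes had a median of -0.616, with 5 of 65 lower (34 adjusted over the list alone, adjusted p = 2.75e-23), but adjusted p = 0.105 with an estimated correlation. The 5 became 0 without T.mu replicate 1 or control replicate 1 or 2, 1 without T.mu replicate 2 or 3 and 3 without control replicate 3, but 11 with DESeq2 or counts halved, 15 with limma voom and 14 with the block or without libraries under 400000 counts. Nuclear-encoded genes of mitochondrial respiration (median -0.340, Cox7c lower 1.98-fold among 53, 14 adjusted over the list alone, adjusted p = 4.8e-06) had adjusted p = 0.32 with an estimated correlation, and mitochondrially encoded genes (median -0.522, 0 of 9, 2 adjusted over the list alone, adjusted p = 0.000331) had adjusted p = 0.377. Goblet cell genes (median -0.265, Tff3 lower among 30, 5 lower and 1 higher adjusted over the list alone, adjusted p = 0.033) and xenobiotic metabolism genes (median -0.231, Cyp2c55 lower among 27, adjusted p = 0.00116) had adjusted p = 0.19 with an estimated correlation. Stem and proliferating cell genes (median 0.450, 0 of 39; Ccna2 at 1.23 and Top2a at 0.88, adjusted p = 0.000525) had adjusted p = 0.105 with an estimated correlation, and cholesterol and lipid synthesis genes (median 0.407, 0 of 29, 1 adjusted over the list alone; Mvk, and Acat2 at 1.18, adjusted p = 0.000115) had adjusted p = 0.19. Fold changes rose with GC content (Spearman 0.32), and the 17 lower genes had a median length of 709 bases against 3495 for all genes.

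What changed in epithelium at day 48? With 4 libraries per arm, 30 of 10119 genes passed, 28 higher and 2 lower. Oasl2 was 6.24-fold higher (log2 2.64 ± 0.32, adjusted p = 1.76e-07), Ifi27l2a 8.96-fold (3.16 ± 0.48, adjusted p = 9.17e-05), Irf7 2.89-fold (1.53 ± 0.25, adjusted p = 0.000187), Oas3 7.17-fold (2.84 ± 0.47, adjusted p = 0.000234). Slfn4, an interferon-induced Schlafen gene, was 3.44-fold higher (1.78 ± 0.30, adjusted p = 0.000397). Cd74 was 16-fold higher (4.00 ± 0.68; 32.96 ± 23.2 CPM against 2.072 ± 3.39, adjusted p = 0.00149). The gasdermin C genes Gsdmc2, Gsdmc3 and Gsdmc4, which encode pore-forming proteins of the gut epithelium, were 2.35-fold (adjusted p = 0.00651), 2.14-fold (adjusted p = 0.0371) and 1.93-fold higher (adjusted p = 0.041). Cd177 was 2.24-fold higher (adjusted p = 0.00918) and the secretory lectin gene Reg4 2.04-fold (730.1 ± 283 CPM against 357.9 ± 87.6, adjusted p = 0.0223). The collagen gene Col8a1 was 3.95-fold lower (adjusted p = 0.00588) and the matricellular gene Ccn3 1.89-fold lower (adjusted p = 0.0223). Retnlb, a goblet cell gene of type 2 immunity, had a mean of 4395 ± 3610 CPM against 608.7 ± 336 and did not pass (log2 2.85 ± 0.83, adjusted p = 0.53), nor did Muc2 (-0.45), Il18 (-0.49) or Igha (1.38, adjusted p = 0.996 each). Of the 20 named genes called, 12 kept their call whichever library was left out. The count was 14 without control replicate 3.

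In epithelium at day 48, 8 of 27 lists were called, 3 with an estimated correlation and 3 by fry. Medians were 1.58 for type I interferon response genes, with 10 of 32 members higher (21 adjusted over the list alone, adjusted p = 5.71e-59), interferon-gamma response genes 1.11, with 2 of 21 (10 adjusted over the list alone, adjusted p = 1.44e-17; 0 without control replicate 3, and 1 without control replicate 1 or 2 or T.mu replicate 2, 3 or 4), and MHC class II genes 1.26, with Cd74 higher among 7 (2 adjusted over the list alone, adjusted p = 6.29e-06; 0 without libraries under 400000 counts). These 3 also held with an estimated correlation (adjusted p = 1.4e-06, 1.87e-06 and 0.00302). Inflammasome and IL-1 family genes (median 0.177, with the 3 gasdermin C genes higher among 22, 4 adjusted over the list alone, adjusted p = 0.00787) had adjusted p = 0.26 with an estimated correlation. Lists with lower values were the enteroendocrine genes (median -0.516; Chgb at -0.76 and Insl5 at -0.55, adjusted p = 0.00787, 0.248 with an estimated correlation), xenobiotic metabolism genes (-0.172; Ces2a at -0.70, adjusted p = 0.0269, 0.428), mitochondrially encoded genes (-0.272, adjusted p = 0.000342, 0.46) and ribosomal protein genes (-0.214; Rpl22 at -0.61, adjusted p = 4.8e-07, 0.483), with 0 members of these past the threshold. Counts halved brought in the antimicrobial and IL-17/IL-22 response genes as higher (adjusted p = 0.0156), and the fit without libraries under 400000 counts the B and plasma cell genes (0.026; 0.0571 each by camera as above). The median of the latter was 1.02, with 0 of 5 members past the threshold. Fold changes rose with GC content here too (Spearman 0.21), and a correction gave 33 genes higher and 9 lower, against 27 and 4 in the block fit.

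**Figure D2:**
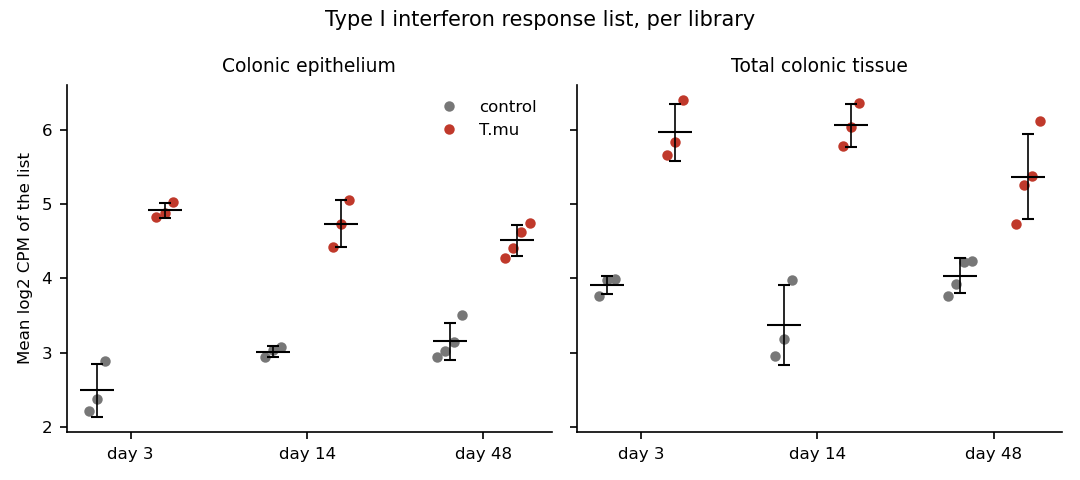
Mean log2 CPM of the type I interferon response list (vertical axis) per library, with group means and SD, for control and T.mu at each day in epithelium and total tissue. At day 3 in epithelium the T.mu mean was 4.916 ± 0.106 against 2.495 ± 0.352, and at day 48 in total tissue 5.371 ± 0.57 against 4.04 ± 0.232.

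What did the mean over the 3 days show in epithelium, and did the effect differ between days? As a mean over days (10 libraries per arm), 343 of 10119 genes passed, 249 higher and 94 lower. Oasl2 was 10.6-fold higher (log2 3.40 ± 0.24, adjusted p = 7.18e-17), Lgals3bp 3.5-fold (1.81 ± 0.15, adjusted p = 5.5e-14), Irf7 3.74-fold (1.90 ± 0.17, adjusted p = 4.46e-13) and Cd177 2.22-fold (1.15 ± 0.17, adjusted p = 2.08e-06). Gsdmd, the pore-forming effector of pyroptosis, rose 1.76-fold (0.81 ± 0.16, adjusted p = 0.000786), Cd74 5.46-fold (2.45 ± 0.45, adjusted p = 0.00144) and Duoxa2, the maturation factor of an epithelial hydrogen peroxide-producing oxidase, 8.69-fold (3.12 ± 0.71, adjusted p = 0.00617). The replication gene Mcm2 was 2.14-fold higher (adjusted p = 0.0154). Ids was 2.33-fold lower (adjusted p = 0.000202), the selenium transport gene Selenop 1.6-fold lower (adjusted p = 0.000727), Insl5 1.7-fold lower (adjusted p = 0.00245), Tff3 1.43-fold lower (adjusted p = 0.027) and mt-Rnr2 1.72-fold lower (adjusted p = 0.014). Of the 52 named genes called, 33 kept their call whichever library was left out. The count was 191 without T.mu day 14 replicate 1, 137 without T.mu day 3 replicate 3, 208, 202 and 590 without T.mu day 48 replicates 1, 3 and 4, 192 without control day 14 replicate 2, 205 without control day 3 replicate 1, and 151 without libraries under 400000 counts. With the litter block the calls of Cnp (adjusted p = 0.102), Gstm3 (adjusted p = 0.0594) and Il18bp (adjusted p = 0.101) ended.

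A difference between days was called for 0 of 10119 epithelial genes by edgeR, with 419 at unadjusted p below 0.05. DESeq2, limma voom and RLE scaling gave 0 each, no filter gave 2, and counts halved, the fit without ribosomal RNA genes and Lars2 and the fit without libraries under 400000 counts gave 1 each. Leaving out T.mu day 3 replicate 2, or T.mu day 48 replicate 1 or 3, gave 1 each.

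What changed in total tissue at day 3? With 3 libraries per arm, 55 of 11696 genes passed, 54 higher and 1 lower. Ifi27l2b was 3.58-fold higher (log2 1.84 ± 0.22; 325.3 ± 81.8 CPM against 91.03 ± 15.4), Ifi44 21.4-fold (4.42 ± 0.56) and Trim30a, a negative regulator of innate signaling, 10.5-fold (3.39 ± 0.42, adjusted p = 3.8e-07 each). Usp18, which removes ISG15 from proteins, was 9.67-fold higher (3.27 ± 0.43, adjusted p = 4.67e-06), Zbp1, a nucleic acid sensor, 4.44-fold (2.15 ± 0.30, adjusted p = 4.33e-06), Oas2 13.3-fold (3.73 ± 0.55, adjusted p = 8.7e-06) and Ly6e 3.14-fold (1.65 ± 0.24, adjusted p = 1.48e-05). The interferon-induced GTPase genes Igtp, Irgm1 and Ifi47 rose 4.18-fold (adjusted p = 0.000249), 3.3-fold (adjusted p = 0.000541) and 2.92-fold (adjusted p = 0.000111). The lower gene was Cyp24a1, the vitamin D hydroxylase gene, by a ratio of 24.5 (95% counting interval 6.56 to 206, adjusted p = 0.0134). Retnlb (log2 -0.42), Reg3g (-0.27) and Cd74 (0.64) each had adjusted p = 0.999. Of the 14 named genes called, 13 kept their call whichever library was left out. DESeq2 gave 87 genes, limma voom 94, only the libraries of this comparison 103 and counts halved 85. The litter block brought in the dermatopontin gene Dpt (log2 0.93 ± 0.24, adjusted p = 0.0834; 0.000361 with the block) and the complement gene C3 (1.60 ± 0.37, adjusted p = 0.0866; 0.0332 with the block).

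In total tissue at day 3, 13 of 31 lists were called, 3 with an estimated correlation and 3 by fry. Type I interferon response genes had a median of 2.12, with 25 of 35 members higher (35 adjusted over the list alone, adjusted p = 4.31e-119), and interferon-gamma response genes 1.11, with 8 of 28 (15 adjusted over the list alone, adjusted p = 8.29e-24; 5 without T.mu replicate 2). Endothelium and lymphatics genes had a median of 0.520, with 0 of 19 members past the threshold (Cd34 at 0.89 and Pdpn at 0.75, adjusted p = 0.00199). These 3 also held with an estimated correlation (adjusted p = 8.26e-05, 0.00741 and 0.0367). Macrophage and dendritic cell genes (median 0.665, 0 of 20, 5 adjusted over the list alone; C1qb at 1.18 and C1qa at 1.13, adjusted p = 1.92e-06) and fibroblast and matrix genes (median 0.535, 0 of 32, 3 adjusted over the list alone, adjusted p = 7.74e-14) had adjusted p = 0.108 with an estimated correlation. Adipocyte genes (median 0.461, 0 of 15, 4 adjusted over the list alone; Car3 at 3.30 and Cfd at 4.14, adjusted p = 0.000113) had adjusted p = 0.25 with an estimated correlation, and smooth muscle genes (median 0.237, adjusted p = 0.000845) had adjusted p = 0.537. Lower medians were called, with their adjusted p under an estimated correlation in second place, for goblet cell genes (-0.277, or -0.202 with absent members at their bound; Zg16 at -0.47 and Capn9 at -1.20, adjusted p = 0.00529, 0.321) and fatty acid oxidation genes (-0.176, adjusted p = 0.0103, 0.43). The same order holds for cholesterol and lipid synthesis genes (-0.168, adjusted p = 0.0481, 0.595), xenobiotic metabolism genes (-0.127; Fmo5 at -0.63 and Gstm3 at -0.75, adjusted p = 0.00296, 0.231), mitochondrially encoded genes (-0.308, adjusted p = 0.00199, 0.328) and ribosomal protein genes (-0.139, adjusted p = 0.00517, 0.561). The litter block brought in the type 2 immune response list (adjusted p = 0.0911; 0.0304 with the block), and counts halved ended the cholesterol call (adjusted p = 0.118) and brought in tuft cell genes as lower (0.172; 0.041 with counts halved). Without libraries under 400000 counts, absorptive colonocyte genes (0.147; 0.0474) and nuclear-encoded respiration genes (0.172; 0.0484) were also called lower.

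What changed in total tissue at day 14? With 3 libraries per arm, 113 of 11696 genes passed, 96 higher and 17 lower (87 and 37 of 124 with RLE scaling). A correction for GC content and length gave 87 higher and 69 lower, against 125 and 27 in the same fit with the litter block and no correction. Of the 33 named genes called, 21 were called after it, 28 in the block fit, and Lypd8 (adjusted p = 0.41), Nfkbiz (0.158) and Cyp51 (0.107) were not. Ifi27l2b was 4.62-fold higher (log2 2.21 ± 0.25) and Oas1a 6.34-fold (2.67 ± 0.30; 138 ± 23 CPM against 20.66 ± 7.86, adjusted p = 2.91e-08 each). Lgals9 was 3.07-fold higher (1.62 ± 0.20, adjusted p = 1.84e-07). Stat2 and Irf9, subunits of the transcription factor of type I interferon signaling, were 6.38-fold (2.67 ± 0.39, adjusted p = 7.92e-06) and 4.62-fold higher (2.21 ± 0.33, adjusted p = 1.18e-05), and Igtp 9.32-fold (3.22 ± 0.48, adjusted p = 1.26e-05). Trim30a was higher by a ratio of 58.1 (95% counting interval 16 to 482). Plac8 was 2.29-fold higher (1.20 ± 0.17; 3475 ± 1140 CPM against 1516 ± 116, adjusted p = 3.7e-06) and Lypd8, a colonocyte protein that keeps flagellated bacteria off the mucosa, 1.78-fold (0.83 ± 0.13; 23760 ± 4190 against 13350 ± 1490, adjusted p = 5.79e-05). The acute phase gene Saa3 was 7.64-fold higher (2.93 ± 0.57; 48.32 ± 32.6 against 7.338 ± 2.09, adjusted p = 0.0015). Casp4, the caspase of the non-canonical inflammasome (known in mice as caspase-11), was 2.34-fold higher (1.23 ± 0.29, adjusted p = 0.011), and Nfkbiz, an epithelial regulator of IL-17 target genes, 2.16-fold (1.11 ± 0.28, adjusted p = 0.0389). Among the lower genes, St3gal5 was 11.7-fold lower (adjusted p = 0.00864), Cmtm8 4.83-fold (adjusted p = 0.00816), the phosphate transporter gene Slc20a1 2.5-fold (adjusted p = 0.0483), the lactate transporter gene Slc16a1 1.72-fold (adjusted p = 0.0398) and Cyp4f15 at least 15.9-fold lower. Retnlb (log2 1.58, adjusted p = 0.519; 1.76, adjusted p = 0.0162 with the litter block), Reg3g (2.81; 2100 ± 2100 CPM against 285.1 ± 247, adjusted p = 0.713), Casp1 (0.51, adjusted p = 0.398) and Cd74 (1.40, adjusted p = 0.773) did not pass. Of the 33 named genes called, 13 kept their call whichever library was left out. The count was 66 without T.mu replicate 2 and 56, 74 and 196 without control replicates 1, 2 and 3. DESeq2 gave 185 genes, limma voom 33 and the fit without libraries under 400000 counts, with 1 control library left, 27. The block ended Cnp (adjusted p = 0.0255; 0.198 with it), Hook3 (0.0206; 0.103), Itga11 (0.03; 0.0853), March6 (0.0383; 0.053) and Sprr1a (0.0499; 0.0618) and brought in mt-Nd5 (log2 -0.57, adjusted p = 0.0741; 0.0167).

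Among 31 lists, 8 were called at day 14 in total tissue, 2 with an estimated correlation and 7 by fry. For type I interferon response genes the median was 2.62, with 27 of 35 members higher (30 adjusted over the list alone, adjusted p = 1.44e-69), and interferon-gamma response genes 1.72, with 10 of 28 (17 adjusted over the list alone, adjusted p = 9.83e-31). With limma voom the 27 became 14 and the 10 became 4, and without libraries under 400000 counts the 27 became 9. These 2 also held with an estimated correlation (adjusted p = 0.00123 and 0.0018). Epithelial antimicrobial and IL-17/IL-22 response genes (median 0.899, 4 of 23 higher, 7 adjusted over the list alone, adjusted p = 1.3e-06; 1 without T.mu replicate 2 or control replicate 3, 2 without T.mu replicate 3 or control replicate 2, and 1 with limma voom to 8 with the block) had adjusted p = 0.209 with an estimated correlation, as had the stem and proliferating cell genes (median 0.525; Cdk1 at 2.11, adjusted p = 0.00452) and the mitochondrially encoded genes (median -0.462, 0 of 9, 7 lower adjusted over the list alone, adjusted p = 1.24e-05). Type 2 immune response genes (median 1.07, or 0.875 with the absent member at its bound, 0 of 8, 1 adjusted over the list alone; Areg at 1.16 and Il4ra at 0.98, adjusted p = 0.00579) had adjusted p = 0.0559 with an estimated correlation. Cholesterol and lipid synthesis genes (median 0.479, Cyp51 1.94-fold higher among 30, 5 adjusted over the list alone, adjusted p = 0.000169; 0 to 3 higher over the alternatives and left-out libraries) and nuclear-encoded genes of mitochondrial respiration (median 0.288, adjusted p = 1.24e-05) had adjusted p = 0.326 with an estimated correlation. The type 2 call also ended without libraries under 400000 counts (adjusted p = 0.55). That fit has 1 control library at this day, assumed to vary like the other groups, and its changes rest on it. It brought in fatty acid oxidation genes (adjusted p = 0.25; 0.0014 in that fit) and tuft cell genes (0.138; 0.0149) as lower and smooth muscle genes as higher (0.59; 0.0437).

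What changed in total tissue at day 48? With 4 libraries per arm, 211 of 11696 genes passed, 117 higher and 94 lower (170 and 89 of 259 with RLE scaling, which moved the median of all genes from -0.106 to -0.0688). Zbp1 was 4.5-fold higher (log2 2.17 ± 0.29, adjusted p = 5.93e-06), Ifi47 3.05-fold (1.61 ± 0.23) and Plac8 1.99-fold (0.99 ± 0.14, adjusted p = 1.27e-05 each). B2m, the light chain of MHC class I, was 1.88-fold higher (0.91 ± 0.13, adjusted p = 1.6e-05). Slc6a14, an epithelial amino acid transporter gene, rose 2.49-fold (1.31 ± 0.17; 2320 ± 482 CPM against 933.1 ± 236, adjusted p = 1.27e-05) and Casp4 2.73-fold (1.45 ± 0.23, adjusted p = 4.05e-05). Jchain, the joining chain of secreted IgA and IgM, was 1.87-fold higher (0.90 ± 0.19, adjusted p = 0.00349). The sterol synthesis genes Msmo1 and Cyp51 were 1.95-fold (adjusted p = 0.00349) and 1.71-fold higher (adjusted p = 0.0292). Lower genes included the mitochondrial genes Chchd10 (2.06-fold lower) and Uqcr11 (2.04-fold lower, adjusted p = 0.000329 each), the metallothionein gene Mt2 (10.4-fold lower; 1.597 ± 3.19 CPM against 32.65 ± 5.34, adjusted p = 0.00056), the ferritin gene Ftl1 (1.87-fold lower, adjusted p = 0.000384), Rpl8 (1.81-fold lower, adjusted p = 0.000597) and Cat, which encodes catalase (1.81-fold lower, adjusted p = 0.00242). Lower genes of the adipocyte list included Fabp4 7.81-fold (33.92 ± 17.7 CPM against 218.9 ± 140, adjusted p = 0.00818), Car3 12.9-fold (45.16 ± 14.3 against 532.7 ± 429, adjusted p = 0.0144), Scd1 6.11-fold (81.08 ± 36.7 against 460.6 ± 295, adjusted p = 0.0176) and Cidec 2.35-fold (adjusted p = 0.00716). The retinol carrier gene Rbp4 (0 counts against 212) was at least 11.8-fold lower. Retnlb (log2 1.22, adjusted p = 0.37; 1.14, adjusted p = 0.0352 with the litter block), the granzyme gene Gzma (1.48, adjusted p = 0.569; 2.26, adjusted p = 0.0489 with the block), Reg3g (2.09, adjusted p = 0.591), Igha (0.62, adjusted p = 0.146) and Cd74 (1.06, adjusted p = 0.621) did not pass. Atp5e (1.47-fold lower, adjusted p = 0.0467) had adjusted p = 0.0547 with the block. Of the 51 named genes called, 30 kept their call whichever library was left out. The count was 138 and 116 without T.mu replicates 2 and 4 and 99 without control replicate 3. DESeq2 gave 364 genes, limma voom 107, only the libraries of this comparison 120 and the fit without libraries under 400000 counts, with 2 T.mu libraries left, 99. The arms of this comparison shared 0 i5 indices, whereas the arms of the 5 other comparisons each shared theirs. Fold changes fell with GC content (Spearman -0.37; median GC 45.7% in the higher genes, 55.3% in the lower and 49.2% in all). A correction for GC content and length gave 552 genes higher and 24 lower, against 142 and 99 in the same fit with the litter block and no correction, so neither the count nor its division by direction is stable. Of the named genes called, 22 of 23 higher ones were called after it, and 6 of 28 lower ones (Rbp4, Mt2, Fabp4, Car3, Scd1 and Nr1d1). Chchd10 went from -1.04 to -0.33, Uqcr11 from -1.03 to -0.21, Ftl1 from -0.90 to -0.17, Rpl8 from -0.85 to -0.10, Cat from -0.85 to -0.52 and Cidec from -1.23 to -0.43. Selenbp1 (-0.59 to 0.03) and Atp5d (-0.57 to 0.24) turned direction.

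For total tissue at day 48, 17 of 31 lists were called, 2 with an estimated correlation and 6 by fry. The camera count was 10 without T.mu replicate 2 and 10 without control replicate 1. Type I interferon response genes had a median of 1.82, with 22 of 35 members higher (30 adjusted over the list alone, adjusted p = 3.13e-58), and interferon-gamma response genes 1.12, with 8 of 28 (15 adjusted over the list alone, adjusted p = 2.36e-21). Without libraries under 400000 counts the 22 became 14 and the 8 became 5. These 2 also held with an estimated correlation (adjusted p = 0.0055 and 0.00994). For the remaining lists the adjusted p with an estimated correlation follows that of camera in each bracket. Adipocyte genes had a median of -1.74, with 7 of 15 lower (11 adjusted over the list alone, adjusted p = 9.99e-11, 0.0772). The number lower was 4 with limma voom, 4 without T.mu replicate 3, 4 without T.mu replicate 4, and 0 of 17 without libraries under 400000 counts, where the median was -2.29. Ribosomal protein genes had a median of -0.431, with 5 of 65 lower (25 adjusted over the list alone; 1.41e-11, 0.175). The 5 became 2 or 3 without T.mu replicate 1, 2 or 4 or control replicate 1 or 3, 9 without T.mu replicate 3, and 1 (limma voom) to 10 (no filter) over the alternatives. Smooth muscle genes (-0.408, Flna 1.75-fold lower among 27; 0.00114, 0.54), fatty acid oxidation genes (-0.186, 3 of 26 lower, 4 adjusted over the list alone; 0.0354, 0.54) and nuclear-encoded respiration genes (-0.213, 3 of 53 lower, 4 adjusted over the list alone; 0.027, 0.666) also had lower medians. Antimicrobial and IL-17/IL-22 response genes had a median of 0.633, with 2 of 23 higher (9 adjusted over the list alone; 6.59e-06, 0.264; 1 without T.mu replicate 2 or 4 or control replicate 1, 3 or 4, 0 without a filter, 7 with DESeq2), inflammasome genes 0.499, with Casp4 higher among 24 (2 adjusted over the list alone; 0.000295, 0.0772), and absorptive colonocyte genes 0.224, with 3 higher and 3 lower among 31 (7 and 4 adjusted over the list alone; 0.00701, 0.4). Cholesterol and lipid synthesis genes had a median of 0.360, with 4 higher and 3 lower among 30 (4 and 5 adjusted over the list alone; 0.0153, 0.54). Without T.mu replicate 2 both became 0; the 4 became 2 without control replicate 1 and 1 without control replicate 3, and the 3 became 1 without T.mu replicate 1 or 3 or control replicate 2 or 4. Paneth cell and small intestine genes had a median of 0.174, with Slc10a2 1.83-fold higher among 13 (2 adjusted over the list alone; 0.0195, 0.54). MHC class II genes (0.878, 0 of 8, H2-Aa at 1.45; 0.0123, 0.4), T and innate lymphoid effector genes (0.827, 0 of 5; 0.0267, 0.37), type 2 immune response genes (0.302, 0 of 8; 0.0354, 0.175) and mitochondrially encoded genes (0.101, 0 of 9; 0.0267, 0.54) had no member past the threshold. B and plasma cell genes were called higher by camera (median 0.393, Jchain higher among 13, 3 adjusted over the list alone; 0.0241, 0.292), while their mean was -0.137. Counts halved ended the type 2 (adjusted p = 0.0731) and Paneth cell calls (0.0856), and the fit without libraries under 400000 counts ended those of the type 2 (0.339), T and innate lymphoid effector (0.214), B and plasma cell (0.0602), Paneth cell (0.145) and mitochondrially encoded (0.216) lists. The latter fit brought in fibroblast and matrix genes as lower (0.0833; 0.0417).

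**Figure D3:**
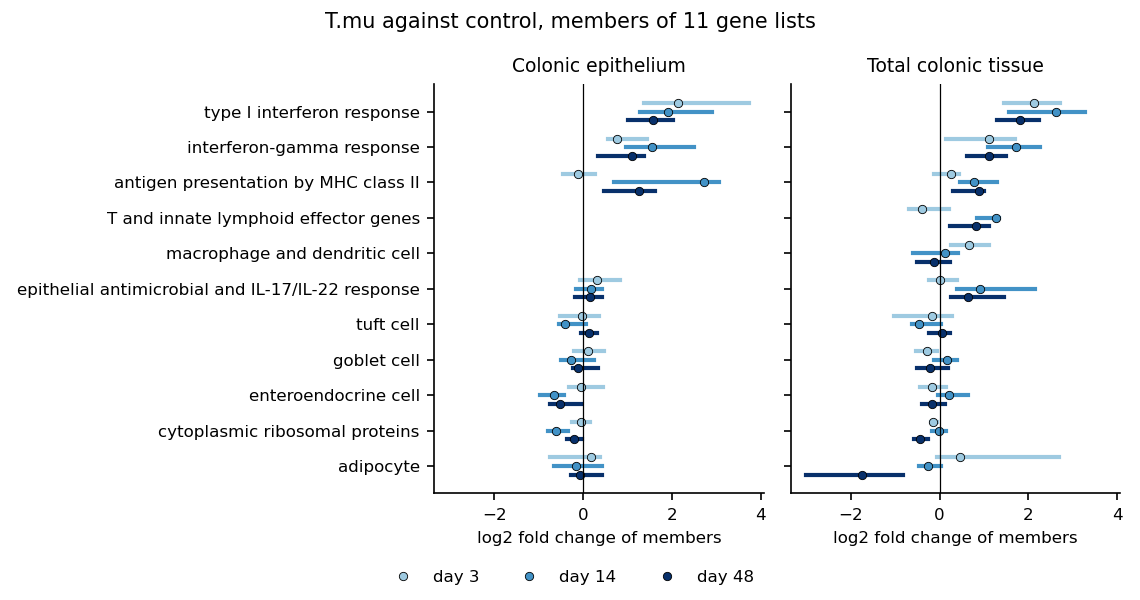
Median (points) and quartiles (bars) of the log2 fold change of T.mu against control over the members of 11 gene lists, by day, in epithelium and total tissue. Type I interferon response genes had medians of 1.58 to 2.62, MHC class II genes in epithelium 2.73 at day 14, and adipocyte genes in total tissue -1.74 at day 48.

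Lists called in no comparison by camera on all libraries and counts were tuft cell, T cell, germinal centre, enteric neuron and glia, ER stress, circadian clock, and immediate early and heat shock genes. Tuft cell genes had medians of -0.03, -0.40 and 0.14 in epithelium and -0.18, -0.47 and 0.05 in total tissue at days 3, 14 and 48, with a lowest adjusted p of 0.138 in total tissue at day 14. They were called lower there without libraries under 400000 counts (0.0149), in a comparison with 1 control library, and at day 3 with counts halved (0.041). T cell genes had medians of 0.31, 0.70 and 0.03 in total tissue (adjusted p = 0.453, 0.797 and 0.369). The lowest adjusted p of immediate early and heat shock genes was 0.0828, in total tissue at day 14. The cytokine genes Il25, Il22, Il17a, Ifng and Il1b and the chemokine gene Cxcl9 had too few counts to be tested in any comparison.

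What did the mean over days show in total tissue? Over 10 libraries per arm, 223 of 11696 genes passed, 175 higher and 48 lower. Ifi27l2b was 3.41-fold higher (log2 1.77 ± 0.13, adjusted p = 4.94e-15), Oas1a 3.62-fold (1.85 ± 0.15, adjusted p = 3.65e-14), B2m 1.85-fold (0.89 ± 0.09, adjusted p = 1.93e-11), Plac8 1.79-fold (0.84 ± 0.09, adjusted p = 4.04e-10), Casp4 1.97-fold (0.98 ± 0.15, adjusted p = 2.85e-06) and Saa3 3.12-fold (1.64 ± 0.27, adjusted p = 2.54e-05). Gsdmd was 1.39-fold higher (0.48 ± 0.12, adjusted p = 0.0102), and Il18bp, which encodes the binding protein of IL-18, had a log2 fold change of 1.44 (adjusted p = 0.0388). Tsku, a secreted regulator of lipid metabolism, was 1.8-fold lower (adjusted p = 0.000102), Cat 1.51-fold lower (adjusted p = 0.000225), Mt2 2.79-fold lower (adjusted p = 0.00193) and Gstm3 1.58-fold lower (adjusted p = 0.0129). Of the 44 named genes called, 31 kept their call whichever library was left out. The fit without libraries under 400000 counts gave 146 genes, and the litter block ended the calls of Cnp (adjusted p = 0.0967) and Tiparp (adjusted p = 0.0876).

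Did the effect in total tissue differ between days? This was called for 8 of 11696 genes. Slc6a14 had log2 fold changes of -0.07, 0.55 and 1.31 at days 3, 14 and 48 (adjusted p = 0.0361), Chchd10 0.46, 0.04 and -1.04 (adjusted p = 0.0133), Uqcr11 0.11, 0.36 and -1.03 (adjusted p = 0.0175), the interferon-induced Ifi27l2a 2.10, 1.33 and -0.36 (adjusted p = 0.0175) and the tight junction gene Cldn3 0.04, 0.57 and -0.61 (adjusted p = 0.0201). Rbp4 had 0.93 and 0.96 at days 3 and 14 and was without counts in the T.mu arm at day 48 (adjusted p = 0.0133), and the microfibril gene Mfap2 had 2.20 and 0.12 at days 3 and 14 and no counts in the T.mu arm against 92 in controls at day 48 (adjusted p = 0.0474). This test was not run with the correction for GC content and length, which took the day 48 values of Chchd10 and Uqcr11 to -0.33 and -0.21 and ended both calls there, and the day 48 arms shared 0 i5 indices. The litter block gave 55 genes, DESeq2 94, limma voom 14, no filter 73 and the fit without libraries under 400000 counts 4. The count was 24 without T.mu day 14 replicate 3, 19 and 5 without T.mu day 3 replicates 2 and 3, 24 and 1 without T.mu day 48 replicates 3 and 4, 76 without control day 14 replicate 3, 14 and 4 without control day 3 replicates 2 and 3, and 17 and 5 without control day 48 replicates 1 and 3.

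**Figure D4:**
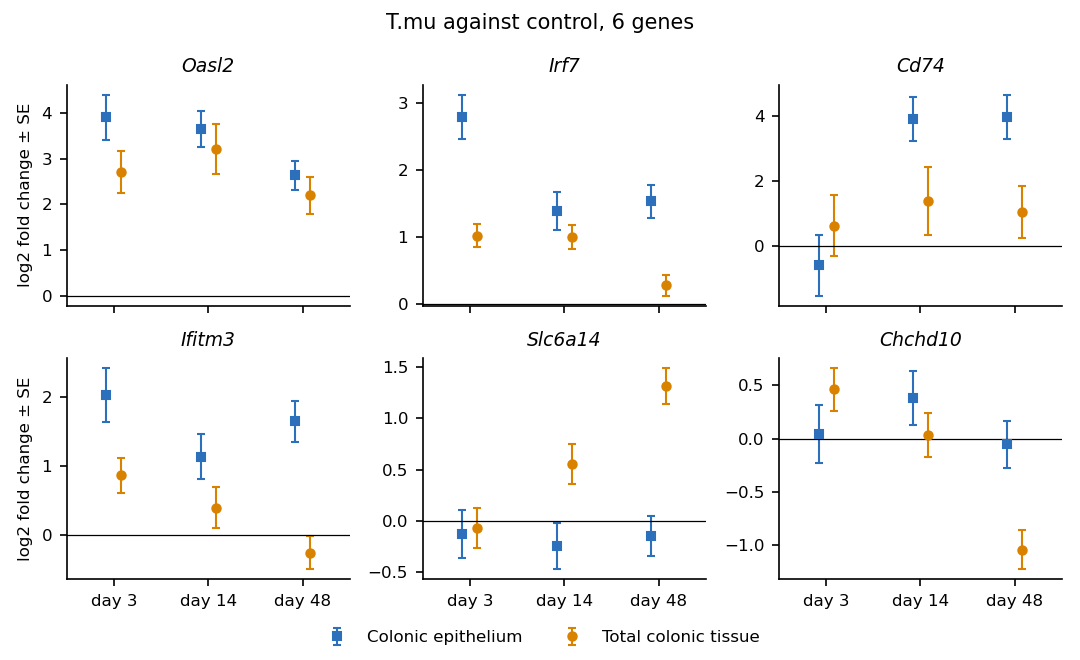
Log2 fold change of T.mu against control with its standard error (vertical axes) for Oasl2, Irf7, Cd74, Ifitm3, Slc6a14 and Chchd10 at each day, in epithelium (squares) and total tissue (circles). In total tissue Slc6a14 went from -0.07 at day 3 to 1.31 at day 48, and Ifitm3 at day 48 stood at 1.65 in epithelium and -0.26 in total tissue. Values are without the GC correction, which takes Chchd10 in total tissue at day 48 to -0.33.

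Where did the response to T.mu differ between epithelium and total tissue? At day 3, 4 of 11834 genes passed, 4 of them larger in epithelium (3 and 1 by direction with RLE scaling, which moved the median of all genes from 0.159 to -0.0637). The difference was 2.84 ± 0.52 in log2 for Gstm3 (2.02 in epithelium and -0.75 in total tissue, adjusted p = 0.00412), 1.85 ± 0.38 for Irf7 (2.80 and 1.02, adjusted p = 0.0241), 4.57 ± 0.96 for the lysosomal transporter gene Spns1 (adjusted p = 0.0289; 0.0936 with a block for the animal) and 1.77 ± 0.38 for the sialidase gene Neu1 (adjusted p = 0.0296; 0.0821 with the block). Gstm3 of these 4 kept its call whichever library was left out. The block gave 2 genes, DESeq2 8, no filter 11, counts halved 1 and limma voom 0. The count was 7 without epithelial T.mu replicate 2, 1, 72 and 1 without epithelial control replicates 1, 2 and 3, 1, 2 and 1 without tissue T.mu replicates 1, 2 and 3, and 2 without tissue control replicate 3.

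At day 14 edgeR called a difference between the tissues for 0 of 11834 genes, with 844 at unadjusted p below 0.05. DESeq2 gave 42, limma voom 0, RLE scaling 0, no filter 2 and the block for the animal 2. The count was 1 without tissue T.mu replicate 1 and 13 without tissue control replicate 3. At day 48, 4 of 11834 genes differed, 3 positive (epithelium minus total tissue) and 1 negative (2 and 4 with RLE scaling). A library batch in tissue stays open (0 shared i5 indices), and no GC correction was run here. The difference was 3.55 ± 0.58 for Ifi27l2a (adjusted p = 0.00179), 1.92 ± 0.40 for Ifitm3 (adjusted p = 0.0207) and -1.43 ± 0.26 for Slc6a14 (adjusted p = 0.00179). Rbp4, absent from T.mu tissue and at 0.17 in epithelium, was positive through its fall in tissue (adjusted p = 0.00322). Of these 4 genes, 3 kept their call whichever library was left out. DESeq2 gave 54 genes (22 positive and 32 negative), no filter 27, counts halved 10 and the fit without libraries under 400000 counts 11. The count was 7 and 15 without tissue T.mu replicates 1 and 3 and 7 without tissue control replicate 1.

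Which genes were shared between the 6 comparisons, which have no libraries in common? The higher calls of days 3 and 14 in epithelium shared 15 genes (0.111 expected if independent), those of days 3 and 48 shared 14 (0.0913) and those of days 14 and 48 shared 18 (0.0941), with 12 on all 3 days. In total tissue the shared counts were 43 (0.443), 38 (0.54) and 51 (0.96), with 33 on all 3 days. Between the tissues 17 genes were shared at day 3 (0.169 expected), 23 at day 14 (0.33) and 12 at day 48 (0.33). Among lower genes Slc20a1 was shared by days 14 and 48 in total tissue (0.137 expected). Higher in all 6 comparisons were 5 genes of the interferon response, placed here on GRCm38: Ifi27l2b (ENSMUSG00000021208, chromosome 12, 103450898 to 103457223, minus strand), Isg15 (ENSMUSG00000035692, chromosome 4, 156199424 to 156200818, minus strand), Oas1a (ENSMUSG00000052776, chromosome 5, 120896256 to 120907521, minus strand), Oasl2 (ENSMUSG00000029561, chromosome 5, 114896936 to 114912234, plus strand) and Rtp4 (ENSMUSG00000033355, chromosome 16, 23520291 to 23614222, plus strand). Expected numbers treat genes as independent, and close copies such as the Ifi27l2 and Oas genes share sequence.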

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

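The tests weighing the 3 patterns here were chosen only after the patterns had been seen. Single libraries were set apart where their distance to the nearest of the 4 libraries of their group was too large a part of the group's range by Dixon's test at 95%. Of 340 such groups of 4 values, 21 passed, against 17 that chance would give at 1 in 20. Groups of 3 were not tested.

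In epithelium at day 48, control replicate 2 had 19673 genes detected, scores of 5.78 for cholesterol and lipid synthesis, 6.86 for xenobiotic metabolism, 8.62 for nuclear-encoded mitochondrial respiration and 8.27 for ribosomal proteins, and Cd74 at 7.08 CPM. Control replicate 4 had Reg3g at 448 CPM. T.mu replicate 4 had 46.6% of its counts on ribosomal RNA genes and Lars2, and T.mu replicate 1 had 417 non-mouse CPM. In total tissue at day 48, control replicate 2 had 969 non-mouse CPM and Nfkbiz at 135 CPM, control replicate 1 had mt-Co1 at 20300 CPM and control replicate 3 had Nr1d1 at 72.9 CPM. Control replicate 4 had a type 2 immune response score of 5.14, Cd74 at 407 CPM, Ftl1 at 551 and H2-Aa at 287. Among T.mu libraries, replicate 3 had Mt2 at 6.39 CPM and Rplp0 at 288, and replicate 4 had Rps26 at 34 and Scd1 at 136.

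Differences between groups passed their own tests for 8 genes between days in total tissue, for 4 genes between tissues at day 3 and for 4 at day 48. A signal outside the mouse genes, above the controls of the same day, was present in the T.mu groups, with mean non-mouse CPM of 1033.1, 747 and 149 in epithelium and 26160, 13794 and 6889.2 in total tissue at days 3, 14 and 48.

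The type I interferon response list was higher in both tissues on all 3 days. Sequencing depth as the cause would need the T.mu arm to be the deeper or the shallower one throughout, and it was deeper in 4 of 6 comparisons. Reads of the inoculum counted on mouse genes would keep the extra list CPM in about 1 ratio to the extra non-mouse counts, and that ratio ran from 0.126 to 5.43, a span of 43.1. More immune cells at an unchanged level per cell stays open as a part of the rise: the lower quartile of the type I list lay above the upper quartile of an immune cell list in 19 of 21 cases, with a lowest gap of -0.18, while its median was higher in all 21 by at least 0.56. These tests argue against depth, and against inoculum reads at 1 ratio over both tissues. They leave T.mu, as the design gives it, beside a change in cell content that could carry part of the signal.

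The raised non-mouse share of 969 CPM in control replicate 2 of total tissue at day 48 was weighed next. Index exchange at one rate would need 16.6% of the non-mouse counts of inoculated libraries sharing an index, against at most 2.29% for any other control, which argues against it. A colonised animal with an interferon response is argued against by a type I score of 4.23, which was 0.499 below the lowest T.mu library of the day (SD of the controls 0.232) and level with the highest other control at 4.23. Mixed-in material at the day's mean T.mu share would need 14.1% of the library (less at a higher share) and raise the score by 0.396. The spread of the controls (lowest 3.76) can neither show nor exclude it. A colonised animal without such a response was not tested.

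In total tissue at day 48, 94 genes were lower, of which 7 were adipocyte genes and 87 were not. For these 87 genes, GC content and transcript length stay open: a correction with the litter block left 50.8% of their median (from -1.16 to -0.589), with 10 called, against 71 in the block fit. For the 7 adipocyte genes the same correction argues against that cause, since the median stayed at -2.03 (quartiles -2.46 and -1.53). A smaller share of fat as the whole cause is argued against for the 87 genes by a median of -1.16 with the adipocyte score as a covariate and the block (quartiles -2.13 and -0.769), although 0 remained called. A library batch marked by the i5 index stays open, since the arms shared 0 indices and the 2 cannot be told apart from the inoculum.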

How the results depend on the processing

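Counts halved and the fits without ribosomal RNA genes and Lars2 or without libraries under 400000 counts were chosen after results had been seen. No called named gene turned direction under the alternatives counted below, the block or a library left out. Top genes were chosen to move the same way in every litter pair. The GC and length correction below turned 2, Selenbp1 and Atp5d at total tissue day 48, and 7 uncalled, with values near 0. Of named genes called, the number no longer past the threshold was 6 with DESeq2, 15 with RLE, 20 with counts halved, 74 with limma voom, 26 without a filter, 29 with only the libraries of the comparison, 94 without libraries under 400000 counts and 6 without ribosomal RNA genes and Lars2, and 10, 2, 4, 9, 7, 9, 1 and 2 others passed. The type I and interferon-gamma lists kept their calls with an estimated correlation in all 6 comparisons. Depth limits which genes can be tested: of 10119 epithelial genes 7281 remained with counts halved, while 12063 were tested without libraries under 400000 counts. The cause of the movements given here was not tested. That fit leaves 1 control library at epithelium day 3 and at total tissue day 14, assumed to vary like the other groups, and 2 T.mu libraries at epithelium day 3 and at total tissue day 48. Its values there, and for means over days and differences between days, say little on depth alone.

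The replicate block (litter) moved the count at epithelium day 14 from 51 to 93 and that of genes differing between days in total tissue from 8 to 55, and the block for the animal moved the differences between tissues at day 3 from 4 to 2 and at day 14 from 0 to 2. The pairing ended 13 calls of named genes and the animal block 4, and 9 others passed, given beside their results in all cases but 1. It also brought in the type 2 immune response list at total tissue day 3 (adjusted p = 0.0304) and changed no other call of a named gene or list.

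DESeq2 gave 42, 8 and 54 genes for the difference between tissues at days 14, 3 and 48, 95 for epithelium day 14, 87, 185 and 364 for total tissue days 3, 14 and 48, and 94 between days in total tissue. Without a filter, the differences between tissues were 2, 11 and 27 at days 14, 3 and 48, and those between days 2 in epithelium and 73 in total tissue. Limma voom gave 0 for the difference between tissues at day 3, 6 and 98 for epithelium days 3 and 14, 94, 33 and 107 for total tissue days 3, 14 and 48, and 14 between days in total tissue. Only the libraries of the comparison gave 12 and 262 for epithelium days 3 and 14 and 103 and 120 for total tissue days 3 and 48.

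A correction for GC content and length with the litter block, also chosen after results had been seen, gave 20, 59 and 33 genes higher and 6, 71 and 9 lower in epithelium at days 3, 14 and 48, and 71, 87 and 552 higher and 1, 69 and 24 lower in total tissue. The same fit without the correction gave 61 and 1 at total tissue day 3, and the other values beside their results. Of named genes called, 13 of 16, 26 of 27 and 20 of 20 in epithelium and 14 of 14, 21 of 33 and 28 of 51 in total tissue were called after the correction. Counts of list members past the threshold were recomputed for 8 of the lists and the larger moves are given beside their results.

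Counts halved gave 1 and 10 for the difference between tissues at days 3 and 48, 20 and 80 for epithelium days 3 and 14, 1 between days in epithelium and 85 for total tissue day 3. Without libraries under 400000 counts the values were 11 for the difference between tissues at day 48, 10 and 90 for epithelium days 3 and 14, 151 for its mean and 1 between its days, and 27 and 99 for total tissue days 14 and 48, 146 for its mean and 4 between its days. Without ribosomal RNA genes and Lars2, 1 gene differed between days in epithelium. For lists, an estimated correlation gave 2, 4 and 3 in epithelium and 3, 2 and 2 in total tissue at days 3, 14 and 48, and fry gave 2, 6 and 3 in epithelium and 3 and 6 in total tissue at days 3 and 48.

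Leaving out each library in turn gave 18 to 52, 19 to 48 and 14 to 28 genes for epithelium days 3, 14 and 48, 137 to 590 for its mean and 0 to 1 between its days. In total tissue the ranges were 56 to 196 at day 14, 99 to 291 at day 48 and 1 to 76 between days, and 10 to 16 for lists at day 48. Differences between tissues ranged from 1 to 72 at day 3, 0 to 13 at day 14 and 3 to 15 at day 48. Counts at total tissue day 3 (41 to 55) and for its mean (169 to 259) and for control epithelium against control tissue (5705 to 6327) stayed within 1.5 times, as did the lists of the 5 other comparisons.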

Other observations

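The genes of the next paragraph and the correlation tests were chosen only after results had been seen; the splits of the samples were fixed before.

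In total tissue, 15 genes outside the interferon lists were higher at days 14 and 48 and were not called at day 3. Among them were the TRIM ubiquitin ligase genes Trim40 (log2 1.41 ± 0.29 and 1.17 ± 0.24 at days 14 and 48) and Trim31 (1.21 ± 0.26 and 0.79 ± 0.21), the hexokinase gene Hk2 (1.23 ± 0.24 and 1.13 ± 0.20, adjusted p = 0.00176 and 0.000283), Dusp6, a phosphatase that acts on ERK kinases (1.07 ± 0.23 and 0.77 ± 0.20) and the tetraspanin-like Tm4sf20 (1.08 ± 0.23 and 0.82 ± 0.19). The lowest adjusted p for a difference between days among the 15 was 0.0999 (Tm4sf20), so a later onset was not shown. In epithelium 0 of the 15 were called at day 14 or 48.

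Did the type I score of inoculated libraries follow the non-mouse share? Over 10 libraries of epithelium, Pearson r with log10 non-mouse CPM was 0.35 (permutation p = 0.321, adjusted 0.321; Spearman 0.552, permutation p = 0.105, adjusted 0.21), and -0.0454 without the 2 farthest libraries (permutation p = 0.91). Over 10 of total tissue it was 0.504 (permutation p = 0.136, adjusted 0.272; Spearman 0.394, permutation p = 0.263, adjusted 0.263), and 0.116 without the 2 farthest (permutation p = 0.773). The hypothesis was neither borne out nor excluded.

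Each count was also computed after splitting the same libraries into other groups. At days 3 and 14 there are 10 splits, too few to judge by. Real and highest other counts of genes were 36 and 3 (epithelium day 3), 51 and 0 (epithelium day 14), 55 and 0 (total tissue day 3) and 113 and 2 (total tissue day 14), those of lists 6 and 7, 11 and 8, 13 and 12, and 8 and 7 in the same order, and those of differences between tissues 4 and 5 at day 3 and 0 and 1 at day 14. The splits at least as high as the real one, itself included, were 1, 1, 1 and 1 for genes, 2, 1, 1 and 1 for lists, and 2 and 10 for differences between tissues.

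At day 48 there are 35 splits, of which 8 part every litter as the real one does. Chance can be excluded for the 30 genes of epithelium (1 of 35 splits as high; highest other 1) but not for its 8 lists (2 of 35; highest other 10, or 7 among those parting every litter). For total tissue it is excluded by that rule for 211 genes (1 of 35; highest other 106, or 0 among those parting every litter) and for 17 lists (1 of 35; highest other 15, or 13). It cannot be excluded for the 4 genes differing between tissues at day 48 (2 of 35; highest other 62, or 0), and that split of 62 points to a structure of the samples. It sets litters 1 and 3 against litters 2 and 4, as does the split that gave 106 genes in total tissue. With the block the real split gave 6 genes differing between tissues and 241 in total tissue; whether the litters cause the high splits was not tested.

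Over all days, the same rule excludes chance for the means over days, with 343 genes in epithelium (1 of 45 splits as high; highest other 37) and 223 in total tissue (1 of 45; highest other 12), and for the 6249 genes between the control preparations (1 of 30; highest other 2423). These splits were drawn without regard to litter, and 1 of 45 or 1 of 30 is the lowest share they can give. Chance cannot be excluded for the 8 genes differing between days in total tissue (3 of 45 splits as high; highest other 29). In epithelium the count was 0, so every split is as high (45 of 45; highest other 14) and nothing is tested. Splits that give 14 and 29 genes where the real ones give 0 and 8 point to a structure of the samples, and what it is was not tested. An earlier, larger draw held splits with still more genes differing between days and left the same results excluded or not.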
